A study of Homo sapiens with 4 samples.

How the data were processed

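The material was RNA of THP-1 cells, 2 libraries with a control LNA and 2 labelled AMANZI knockdown, all treated with LPS. Per the labels' protocols, polyadenylated RNA was made into libraries with a stranded Illumina messenger RNA kit. The authors deposited a single table of whole-number counts per gene, 64479 genes by 4 libraries, with no normalisation. Per the submitters' processing notes, fastp, STAR, HTSeq and DESeq2 were named as tools and hg19 as the genome build. Their versions, the annotation release and the strand setting of the counting are not given in the sources used here. A wrong strand setting would misplace reads of overlapping and antisense genes, and reads shared between near-identical copies could be lost or split at counting. All 4 columns carried sample names that matched the labels, and every row named a gene.

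Gene identifiers were used as given. Of 64479 identifiers, a table of gene names paired 40939 with a symbol and GENCODE release 29 a further 63, and 23477 had none. Because the references at hand are of GRCh38, no coordinates are given, and RefSeq's GRCh38.p14 gene table was used only for names and neighbours. AMANZI had no row under its symbol, and the gene lying within it was used in its place.

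Genes were compared with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, estimateDisp, glmQLFit and glmQLFTest with the installed defaults). The groups were the only term in the model. Benjamini-Hochberg adjusted p under 0.05 was the threshold, over the 17032 of 32260 genes above 0 counts that passed the filter. TMM factors lay between 0.990 and 1.01, and the common coefficient of variation was 7.72%. Levels are CPM after TMM scaling, with the SD over the 2 libraries of a group, and library shares are percent of all counts. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Within-group counts differed by more than sampling noise (chi-square per gene of 4.53 in the control pair and 3.31 in the other), so each library was counted once. The 3-count floors cover counting error only.

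A total of 43 gene lists was fixed before the data were examined, with 1227 memberships, of which 1197 matched by symbol, 21 by an older symbol and 9 not at all. Lists with at least 5 tested members (40) were compared with all other genes by limma's camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, adjusted over the 40 lists. Of these, 20 were higher and 5 lower, and none of the 25 calls held with an estimated correlation. For each list the members called over all genes tested were counted, and those called when adjusted over the list alone. Some genes, among them IL1B, FN1 and ATF3, belong to several lists, so the counts overlap and the lists are not independent.

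The genes to be named were also set by rule: the targeted RNA and 8 interleukin, chemokine and TNF genes whatever their values. Next came the 10 highest and 10 lowest log2 fold changes among called genes with non-overlapping groups and a mean of at least 2 CPM. Then came up to 4 members of each list with the smallest p, and any member needed to describe a split. Other members are named with values only, and a few genes that met the rule are not reported here.

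The procedure was tested on simulated counts with the real means and library sizes of this comparison over 17032 genes. It recovered 50.7% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 90.9% of those changed 4-fold. Of 152 calls 6 were false, and no gene was called where nothing had been changed. The simulated genes varied independently at the fitted dispersion trend with no replicate effect, so these rates need not hold for the real calls. Alternatives were median-of-ratios and no scaling, no filter and a filter at 5 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out, glmTreat at 1.5-fold, an adjusted p of 0.01, an estimated correlation and fry. With a library left out, its group's other sample is assumed to vary like the other group. A GC correction and the newer quasi-likelihood setting were added after the data were seen.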

Results

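Gene expression was measured by RNA sequencing in THP-1 cells, a human monocytic leukaemia line. The cells had received an antisense oligonucleotide of the LNA gapmer type, whose DNA core lets RNase H cut the RNA it binds. In 2 libraries the oligonucleotide was directed at AMANZI, a long noncoding RNA, and in 2 it was a control LNA. All cells were held with the LNA for 24 hours and then with 10 ng/ml of lipopolysaccharide (LPS), a bacterial ligand of the receptor TLR4, for a further 24 hours. No unstimulated library was analysed here. The libraries held 9452605 and 9546843 counts in the control group and 9327374 and 8237714 in the group labelled AMANZI knockdown. Between 26632 and 27013 genes had at least 1 count in a library. A count of 3 corresponded to 0.314 to 0.364 CPM, which are counts scaled to the library total. The comparison asks how the messenger RNA profile of LPS-stimulated monocytic cells differs when AMANZI is depleted.

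The targeted RNA was examined first. AMANZI was not named by symbol in the count table, but the gene ENSG00000280228.1_7 lies entirely within it in RefSeq's GRCh38.p14 annotation and covers 87.7% of its length. It neighbours IL1B, on the side of IL37. Counts of this region were 39 and 23 in the control libraries and 58 and 55 in the libraries labelled AMANZI knockdown. Its level was 3.28 ± 1.2 CPM (SD, n = 2) in the control group and 6.46 ± 0.32 CPM (SD, n = 2) in the labelled knockdown group. ENSG00000280228 was therefore higher, not lower, in the libraries labelled knockdown, with a log2 fold change of 0.97 (SE 0.27, adjusted p = 0.0347, edgeR). That call was lost without control replicate 2 (0.65, adjusted p = 0.173), without knockdown replicate 1 (adjusted p = 0.156) and without knockdown replicate 2 (adjusted p = 0.0755). Whether the annotated gene and AMANZI are read from the same strand is not given in the sources used here. Because the measured region went against the label, directions below are those of the libraries labelled AMANZI knockdown against the control libraries and are not evidence of depletion.

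IL1B, which encodes the inflammatory cytokine interleukin-1 beta, had the clearest rise among the genes fixed for inspection. It stood at 25.3 ± 0.099 CPM (SD, n = 2) in the control group and 92.7 ± 2.4 CPM (SD, n = 2) in the libraries labelled knockdown. Its log2 fold change was 1.87 (SE 0.11, adjusted p = 1.25e-06). IL1RN, which encodes the antagonist of the interleukin-1 receptor, rose from 22.7 ± 0.038 to 47.3 ± 0.23 CPM (log2 fold change 1.06, SE 0.12, adjusted p = 0.00011). TNF, another early inflammatory cytokine, went the other way, from 10.6 ± 1.6 to 4.5 ± 0.17 CPM (log2 fold change −1.24, SE 0.22, adjusted p = 0.00237). CXCL8, a neutrophil chemokine, stood at 61.9 ± 31 and 99.7 ± 14 CPM and did not pass the test (log2 fold change 0.69, adjusted p = 0.073). It passed in 6 of 16 alternatives: with no composition factor (adjusted p = 0.0477), limma-voom (adjusted p = 0.0477), the GC correction (adjusted p = 0.0125) and the replicate block (adjusted p = 2.58e-05), and without control replicate 2 or knockdown replicate 2. The CXCL8 controls held 376 and 793 counts. Without control replicate 1 its log2 fold change was 0.25 (adjusted p = 0.196), without control replicate 2 1.33 (adjusted p = 4.57e-19), without knockdown replicate 1 0.83 (adjusted p = 0.197) and without knockdown replicate 2 0.54 (adjusted p = 0.0332). IL1A was near the detection limit, at 1.06 ± 0.75 and 1.49 ± 1.2 CPM, and did not differ beyond its spread (adjusted p = 0.64).

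IL37, IL6 and IL10 were too low to test. IL37, an anti-inflammatory relative of IL1B, had 5 and 4 counts in the controls and 6 and 3 in the labelled knockdown libraries. IL6 had 1 and 5 counts against 7 and 1, and IL10 had 1 count in all 4 libraries together. Differences in these 3 genes were not detectable at this depth. Of the 17 genes listed for the chromosomal neighbourhood of IL1B, 10 were measured, and IL1B and IL1RN rose. In all, 4 rose and 1 fell adjusted over the list alone. The list passed as a higher set by camera (adjusted p = 0.000103, or 0.269 with an estimated correlation). Of its members, 7 had a log2 fold change above 0 and 3 below. The list was not tested without IL1B and IL1RN. Without control replicate 1, or without knockdown replicate 2, 4 of its members rose, and without control replicate 1, 1 fell.

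**Figure D1:**
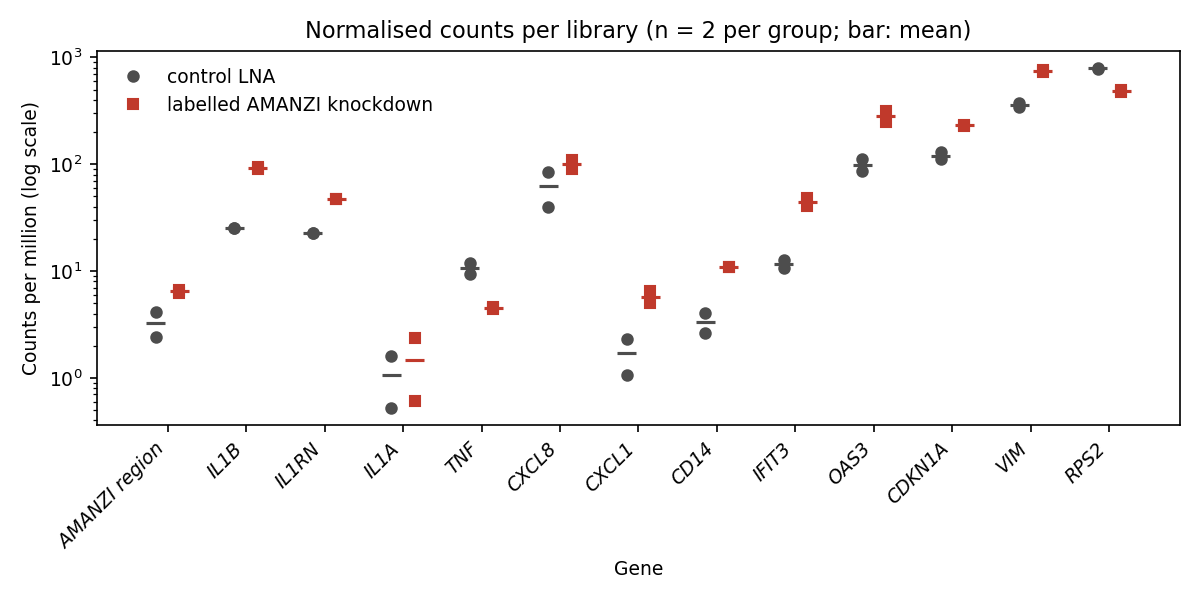
Level in CPM after library scaling (log axis) for 13 genes in each of the 4 libraries. Circles are control LNA libraries, squares the libraries labelled AMANZI knockdown, and bars the means (n = 2 per group). IL1B lies at 25.3 CPM on average in the control libraries and 92.7 CPM in the labelled knockdown libraries, TNF at 10.6 and 4.5 CPM, and the AMANZI region at 3.28 and 6.46 CPM.

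Across 17032 tested genes, 1058 rose and 858 fell in the libraries labelled AMANZI knockdown. Of these, 307 rose and 181 fell by at least 2-fold. Samples separated by group along the first principal component, which held 61.8% of the variance. The second component (21.1%) separated replicate 1 from replicate 2 in both groups. The deviations of same-numbered libraries correlated only weakly (0.108), which by itself can give that split. With the replicate number as a block 1710 genes were higher and 1550 lower. CEMIP, which encodes a hyaluronan-binding protein, had the largest rise among genes with a mean of at least 2 CPM, from 0.371 ± 0.23 to 7.85 ± 1.8 CPM (log2 fold change 4.36, SE 0.41, adjusted p = 3.7e-05). Its control level lay near the 3-count floor of the control libraries (0.317 and 0.314 CPM), so the size of the rise is uncertain. CR1, a receptor for complement fragments, rose from 1.06 ± 0.15 to 12.3 ± 1.2 CPM (log2 fold change 3.52, SE 0.27, adjusted p = 1.17e-05). The other 8 were SPOCD1 (3.37), KLHDC7B (2.75), DYSF (2.65), the transcription factor SNAI2 (2.59), FGL1 (2.47), the collagenase MMP1 (2.47), the potassium channel KCNK10 (2.37) and fibronectin, FN1 (2.28). DYSF and MMP1 were no longer called without knockdown replicate 1 (adjusted p = 0.0686 and 0.0583). Leaving out control replicate 2 moved the log2 fold change of CEMIP to 5.14, SPOCD1 to 4.23, FGL1 to 3.39 and DYSF to 4.50, and leaving out control replicate 1 moved DYSF to 1.87. In total 384 genes rose and 190 fell without knockdown replicate 1, and without knockdown replicate 2, 698 rose and 559 fell.

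Among the 10 genes that fell most under the same rule, 5 encode proteins and 5 are noncoding or pseudogene transcripts. TRD-AS1, an antisense transcript at the T cell receptor delta locus, fell from 33.6 ± 3 to 7.5 ± 0.64 CPM (log2 fold change −2.16, SE 0.16, adjusted p = 1.17e-05). HIF1A-AS3, annotated antisense to HIF1A, fell from 87.4 ± 26 to 20.7 ± 2.2 CPM (log2 fold change −2.08, SE 0.18, adjusted p = 2.01e-05). The strand setting of the counting is not given in the sources used here, so reads of an antisense gene and its partner may not be fully separated. ADGRB3-DT had the largest fall (log2 fold change −2.82) and the processed pseudogene ENSG00000237444 one of −2.26, a value left uncertain by reads that such copies share with their parent genes. ENSG00000230379 had a log2 fold change of −2.66. The protein-coding genes were CPS1, a urea cycle enzyme (−2.72), STXBP6 (−2.37), the actin regulator CYFIP2 (−2.10), KIF26A (−2.03) and the spectrin gene SPTB (adjusted p = 0.00111). Leaving out knockdown replicate 1 moved CYFIP2 to −2.79 and SPTB to −2.65, and leaving out knockdown replicate 2 moved KIF26A to −2.68.

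**Figure D2:**
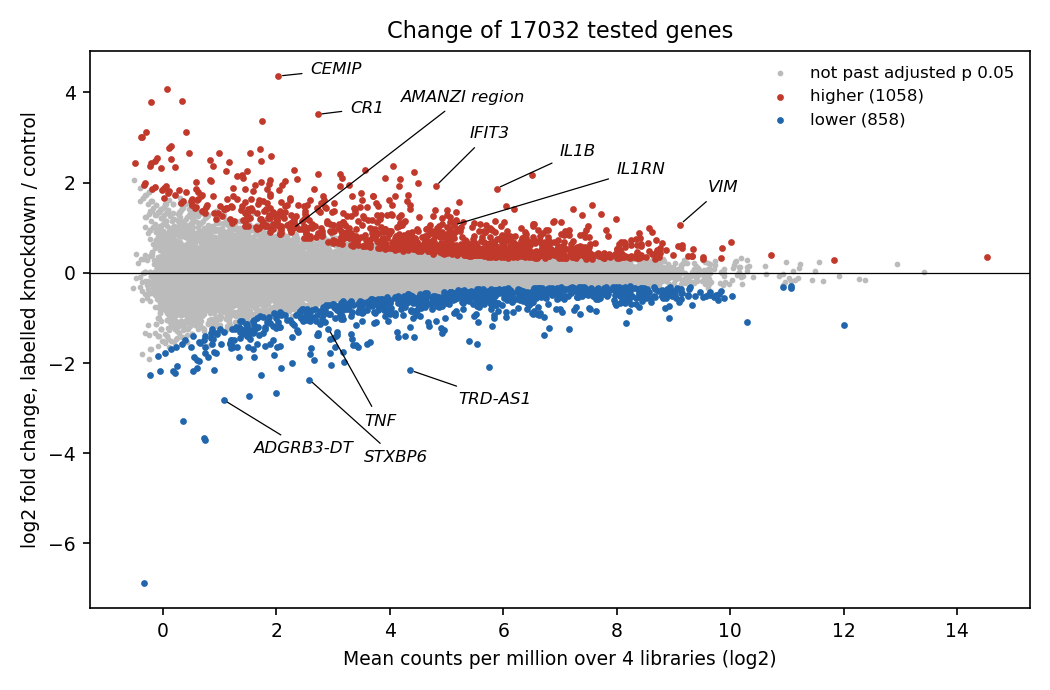
Log2 fold change of each of 17032 tested genes, libraries labelled AMANZI knockdown against control, on its mean level over 4 libraries (log2 CPM). Red points (1058) were higher and blue points (858) lower past an adjusted p of 0.05; IL1B lies at 1.87, CEMIP at 4.36, TNF at −1.24 and the AMANZI region at 0.97.

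The inflammatory gene lists were higher as sets in the libraries labelled AMANZI knockdown, with a minority of their members called. Of 18 measured pro-inflammatory cytokines and chemokines, 7 rose and TNF fell. Only 3 rose with DESeq2 and 1 with no filter or by glmTreat, against 10 with the replicate block. The list's median log2 fold change was 0.65, 0.71 with no filter and 0.33 without control replicate 1. CXCL1, a neutrophil chemokine, rose from 1.69 ± 0.91 to 5.75 ± 0.99 CPM (log2 fold change 1.75), or by 2.43 without control replicate 2. IL23A, a subunit of interleukin-23, rose by 0.73 on the log2 scale but not without knockdown replicate 2 (adjusted p = 0.0522). In all, 9 cytokine genes rose and 2 fell adjusted over the list alone. The list was higher as a set (adjusted p = 2.93e-06; adjusted p = 0.375 with an estimated correlation). Of 22 genes of NF-kB and its feedback, 7 rose, among them the inhibitor family member NFKBIZ (0.90, adjusted p = 0.000137) and the adaptor TRAF1 (0.80, adjusted p = 0.0026). In all, 8 NF-kB genes rose adjusted over the list alone, and the set was higher (adjusted p = 5.89e-05; adjusted p = 0.269 with an estimated correlation). In each of these 2 lists, 3 genes rose without knockdown replicate 1, and 2 cytokine genes fell without control replicate 1.

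The lists of the LPS receptor pathway and the inflammasome were also higher as sets. The co-receptor CD14 rose from 3.33 ± 0.99 to 10.9 ± 0.099 CPM (log2 fold change 1.70, SE 0.24, adjusted p = 0.000469). The adaptor MYD88 rose by 0.65 and the kinase IRAK1 by 0.59, and TLR4 itself by 0.81, which did not hold without knockdown replicate 1 (adjusted p = 0.116). Of 26 genes of TLR4 signalling, 5 rose and none fell, and 10 rose adjusted over the list alone. The set was higher (adjusted p = 0.000136; adjusted p = 0.269 with an estimated correlation). Of 21 inflammasome and pyroptosis genes, 7 rose, including IL1B and the DNA sensor IFI16 (0.79, adjusted p = 0.00098), while NLRP3 and CASP1 had log2 fold changes of −0.08 and 0.07. In all, 7 inflammasome genes rose and 1 fell adjusted over the list alone. That set was higher too (adjusted p = 2.67e-05; adjusted p = 0.269 with an estimated correlation). The members that rose were 3 TLR4 signalling genes and 4 inflammasome genes without knockdown replicate 1, and without knockdown replicate 2, 3 inflammasome genes. Also, 1 inflammasome gene fell without control replicate 1.

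The lists of genes that restrain inflammation and of immediate early genes passed as higher sets, with members called in both directions. Of 28 anti-inflammatory genes, 11 rose and NR4A1 fell (−0.60). ATF3, a stress-induced repressor of cytokine genes, rose from 11.1 ± 0.8 to 29.7 ± 0.071 CPM (log2 fold change 1.42, adjusted p = 7.19e-05). ANXA1 rose by 0.87 and IL4R by 0.66 on the log2 scale. In all, 13 rose and 3 fell adjusted over the list alone, and the set was higher (adjusted p = 0.000295; adjusted p = 0.375 with an estimated correlation). Of 30 AP-1 and immediate early genes, 10 rose and 2 fell. FOS rose by 0.81 and the phosphatase DUSP4 by 0.66, whereas the transcription factor EGR3 fell from 15.4 ± 1.2 to 5.08 ± 0.04 CPM (log2 fold change −1.60, adjusted p = 0.000149). Adjusted over the list alone, 14 rose and 3 fell, with the set higher (adjusted p = 0.000295; adjusted p = 0.381 with an estimated correlation). In each list 5 genes rose without knockdown replicate 1, where NR4A1 was not called (adjusted p = 0.258), and without knockdown replicate 2, 6 AP-1 genes rose. Genes that fell numbered 5 in each list without knockdown replicate 2, 3 anti-inflammatory and 4 AP-1 genes without control replicate 1, and 2 anti-inflammatory genes without control replicate 2. In the anti-inflammatory list, 11 of 28 genes had a log2 fold change below 0. The median was 0.09, and 0.04 to 0.34 with a library left out (lowest without knockdown replicate 2, highest without control replicate 2).

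Interferon-stimulated genes had the largest median log2 fold change of the lists tested. Of 47 measured, all 47 had a log2 fold change above 0, 38 rose and none fell, with a median of 0.93 and an SD over genes of 0.75. IFIT3, an antiviral protein, rose from 11.7 ± 1.3 to 44.4 ± 5.1 CPM (log2 fold change 1.92, SE 0.15, adjusted p = 1.17e-05). OAS3, which senses double-stranded RNA, rose from 98.7 ± 17 to 281 ± 47 CPM (log2 fold change 1.51, SE 0.13, adjusted p = 2.23e-05). IFIT2 and TRIM22 rose by 2.08 and 2.09. In all, 44 rose adjusted over the list alone, and the set was higher (adjusted p = 4.84e-58; adjusted p = 0.269 with an estimated correlation). IFNB1, which encodes interferon beta, had 1 and 1 counts in the controls and 2 and 5 in the labelled knockdown libraries, too few to test, and IFNA1 had none in any library.

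Related antiviral and antigen presentation genes followed in part, in lists that share members. TAP1, TAP2 and NLRC5 were listed for both the interferon gamma response and MHC class I presentation. DDX58 and IFIH1 were listed for both interferon-stimulated genes and nucleic acid sensing. Of 18 genes of the interferon gamma response, 7 rose and WARS1 and IRF8 fell (−0.32 and −0.33), with the same counts adjusted over the list alone. The guanylate-binding protein GBP5 rose from 3.54 ± 0.51 to 10.8 ± 0.14 CPM (log2 fold change 1.61, adjusted p = 0.000402) and LAP3 by 1.04. WARS1 and IRF8 were not called without knockdown replicate 1 (adjusted p = 0.247 and 0.147), knockdown replicate 2 (adjusted p = 0.128 and 0.254) or control replicate 1 (adjusted p = 0.103 and 0.0959). The set was higher (adjusted p = 9.09e-06; adjusted p = 0.269 with an estimated correlation). Of 22 genes of nucleic acid sensing, 11 rose and 3 fell. The RNA receptor TLR7 rose from 5.08 ± 0.62 to 17.5 ± 0.82 CPM (log2 fold change 1.78, adjusted p = 7.8e-05), and the lysosomal ribonuclease RNASET2 fell from 121 ± 6.4 to 64.2 ± 6.1 CPM (log2 fold change −0.91, adjusted p = 0.000137). In all, 12 rose and 4 fell adjusted over the list alone, with the set higher (adjusted p = 0.00029; adjusted p = 0.279 with an estimated correlation). PLD4 and STING1 also fell (−0.38 and −0.39), but not without knockdown replicate 1 (adjusted p = 0.353 and 0.195), nor STING1 without knockdown replicate 2 (adjusted p = 0.0537). In this list 4 genes rose without knockdown replicate 1, 5 without knockdown replicate 2 and 7 without control replicate 1.

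Of 14 genes of MHC class I presentation, 4 rose. They were TAP1 (0.77), the regulator NLRC5 (0.71, adjusted p = 0.000572), the chaperone CALR (0.59) and B2M (0.38), while HLA-B and HLA-C had log2 fold changes of 0.11 and −0.22. Without knockdown replicate 1, fewer genes of the list rose, and CALR and B2M were no longer called. TAP1 was lost without knockdown replicate 2 (adjusted p = 0.0877) and B2M without control replicate 1 (adjusted p = 0.0527). In all, 5 rose adjusted over the list alone, and the set was higher (adjusted p = 0.00109; adjusted p = 0.269 with an estimated correlation). Of 8 MHC class II genes, the lipid-presenting CD1D came nearest to the edgeR threshold (−0.66, adjusted p = 0.0518), and without control replicate 2, 1 of the genes fell. In all, 1 fell adjusted over the list alone. The median of that list was 0.04 (−0.05 without knockdown replicate 1 and 0.15 without control replicate 2) and its mean −0.02, and it did not pass the set test (direction down, adjusted p = 0.665).

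**Figure D3:**
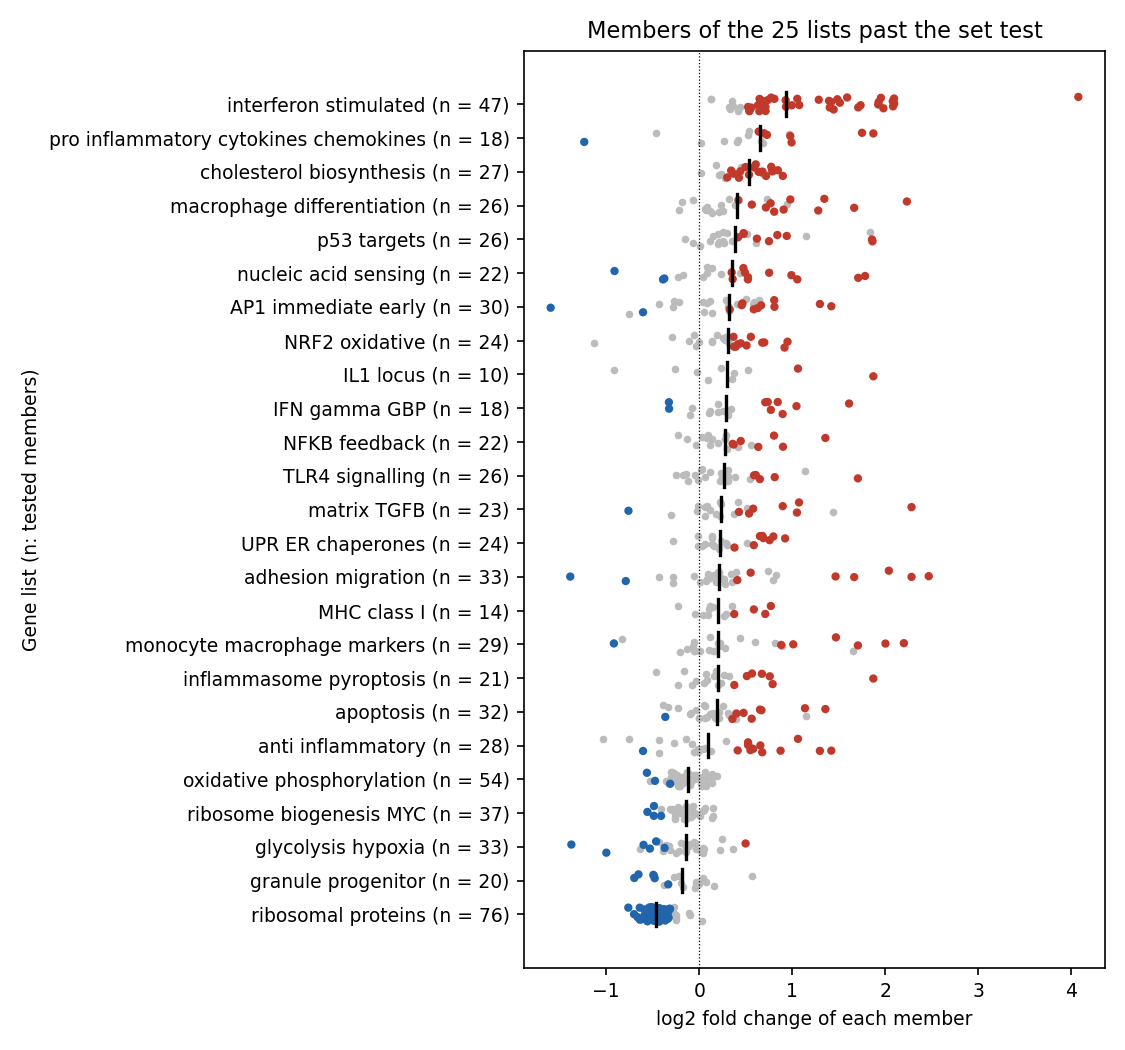
Log2 fold change, libraries labelled AMANZI knockdown against control, of each tested member of the 25 gene lists that passed the set test. Red and blue points passed an adjusted p of 0.05 as higher and lower, grey points did not, and black bars are list medians, from 0.93 for interferon-stimulated genes to −0.47 for ribosomal proteins.

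The lists of macrophage differentiation, adhesion and matrix genes were higher as sets in the libraries labelled AMANZI knockdown. Of 26 differentiation genes, 11 rose and none fell. The membrane protein EMP1 rose from 7.52 ± 2 to 35.4 ± 4.1 CPM (log2 fold change 2.23, adjusted p = 1.5e-05), and cathepsin L, CTSL, by 0.91. In all, 15 rose adjusted over the list alone, with the set higher (adjusted p = 3.29e-12; adjusted p = 0.269 with an estimated correlation). Of 29 monocyte and macrophage markers, 6 rose and VCAN, a matrix proteoglycan, fell from 213 ± 29 to 113 ± 2.3 CPM (log2 fold change −0.92, adjusted p = 0.000138). The calcium-binding alarmin S100A9 rose from 9.1 ± 0.4 to 36.3 ± 9.7 CPM (adjusted p = 3.95e-05) and the scavenger receptor CD36 by 1.01. Adjusted over the list alone, 8 markers rose and 2 fell, and the set was higher (adjusted p = 0.000136; adjusted p = 0.269 with an estimated correlation). Only 6 differentiation genes rose without knockdown replicate 1, and 1 fell without control replicate 1, where 2 markers fell, as they did without knockdown replicate 2.

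Of 33 adhesion and migration genes, 7 rose and 2, ITGA2 (−1.39) and ADAMTS4 (−0.79), fell. FN1 rose from 4.02 ± 0.77 to 19.7 ± 3.2 CPM (adjusted p = 3.13e-05), the integrin subunit ITGB7 by 1.46 and the gelatinase MMP9 by 1.66. In all, 11 rose and 3 fell adjusted over the list alone, and the set was higher (adjusted p = 5.84e-05; adjusted p = 0.269 with an estimated correlation). Of 23 matrix and TGF-beta genes, 7 rose and LTBP3 fell (−0.76). Vimentin, VIM, an intermediate filament protein, rose from 358 ± 25 to 752 ± 20 CPM (log2 fold change 1.07, SE 0.09, adjusted p = 2.01e-05), and the collagen genes COL6A1 and COL6A2 rose by 1.05 and 0.90. In all, 8 matrix genes rose and 1 fell adjusted over the list alone, and that set was higher (adjusted p = 1.09e-06; adjusted p = 0.269 with an estimated correlation). Without knockdown replicate 1, 4 adhesion genes rose, and ITGA2, ADAMTS4 and LTBP3 were not called (adjusted p = 0.168, 0.0905 and 0.104). LTBP3 was not called without knockdown replicate 2 (adjusted p = 0.0868), nor ITGA2 without control replicate 2 (adjusted p = 0.0626).

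Several lists of stress and metabolic genes were higher as sets. Of 27 genes of cholesterol biosynthesis, 20 rose and all 27 had a log2 fold change above 0, with a median of 0.53. Among them, ACAT2 and LSS rose by 0.77 and 0.84. The list's median was 0.42 without control replicate 1 and 0.73 without control replicate 2. With no filter 6 rose and by glmTreat at 1.5-fold 0, against 22 with the replicate block. In all, 22 rose adjusted over the list alone, and the set was higher (adjusted p = 1.47e-16; adjusted p = 0.269 with an estimated correlation). Of 26 p53 target genes, 9 rose and none fell. The cell cycle inhibitor CDKN1A rose from 120 ± 12 to 231 ± 3.8 CPM (log2 fold change 0.94, adjusted p = 8.43e-05) and the secreted factor GDF15 from 2.75 ± 0.88 to 10 ± 0.31 CPM (log2 fold change 1.86). In all, 11 p53 targets rose adjusted over the list alone, with the set higher (adjusted p = 1.07e-08; adjusted p = 0.269 with an estimated correlation). Cholesterol genes that rose numbered 10 without knockdown replicate 1, and without knockdown replicate 2, 12.

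Of 32 apoptosis genes, 8 rose and the survival factor BCL2 fell (−0.37). The death ligand TNFSF10 rose from 8.57 ± 0.41 to 18.8 ± 1.5 CPM (log2 fold change 1.14, adjusted p = 0.00074) and the BCL2 antagonist BCL2L11 by 0.65. In all, 11 rose and 1 fell adjusted over the list alone, and the set was higher (adjusted p = 0.000524; adjusted p = 0.269 with an estimated correlation). Of 24 endoplasmic reticulum chaperone and unfolded protein response genes, 8 rose and none fell. HSPA5, the main chaperone of that compartment, rose from 292 ± 19 to 459 ± 17 CPM (log2 fold change 0.65, adjusted p = 0.000538) and the stress sensor ERN1 by 0.76. Adjusted over the list alone, 10 chaperone genes rose and 1 fell, with the set higher (adjusted p = 1.16e-06; adjusted p = 0.269 with an estimated correlation). Of 24 NRF2 and oxidative stress genes, 11 rose and none fell, and SLC7A11, a cystine transporter, rose from 98.1 ± 4.2 to 189 ± 10 CPM (log2 fold change 0.95, adjusted p = 6.79e-05). In all, 15 NRF2 genes rose and 1 fell adjusted over the list alone (set adjusted p = 1.67e-06; adjusted p = 0.269 with an estimated correlation). The members that rose numbered 2 apoptosis genes, 3 chaperone genes and 2 NRF2 genes without knockdown replicate 1. BCL2 was not called without knockdown replicate 1 or 2 (adjusted p = 0.107 and 0.17), and without control replicate 1, 1 NRF2 gene fell.

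Ribosomal protein genes fell together. Of 76 measured, 63 fell and none rose, with a median log2 fold change of −0.47 and an SD over genes of 0.13. RPS2 fell from 792 ± 12 to 487 ± 16 CPM (log2 fold change −0.70, SE 0.09, adjusted p = 0.000196) and RPSA from 421 ± 39 to 248 ± 28 CPM (log2 fold change −0.76, SE 0.10, adjusted p = 0.000468). These genes held 3.31 and 3.09% of all counts in the control libraries and 2.43 and 2.18% in those labelled knockdown. In all, 73 fell adjusted over the list alone, and the set was lower (adjusted p = 1.05e-38; adjusted p = 0.269 with an estimated correlation). Some of these genes have many processed pseudogenes that can share their reads. The number that fell was 39 without knockdown replicate 1, and without knockdown replicate 2, 35.

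Other groups that were lower as sets had few called members. Of 20 granule and progenitor genes, 6 fell and none rose, including the granule protease PRTN3 (−0.70, adjusted p = 0.00138) and the receptor FLT3 (−0.65, adjusted p = 0.00383, or 0.0797 without knockdown replicate 1). In all, 7 fell adjusted over the list alone (set adjusted p = 0.00243; adjusted p = 0.269 with an estimated correlation). Of 33 glycolysis and hypoxia genes, 6 fell and HIF1A rose (0.50). NDRG1 fell from 646 ± 140 to 324 ± 60 CPM (adjusted p = 0.000621) and the histone demethylase KDM3A by 0.60. In all, 9 of these fell and 1 rose adjusted over the list alone (set adjusted p = 0.00134; adjusted p = 0.429 with an estimated correlation). Without knockdown replicate 1 that set was no longer lower (adjusted p = 0.103) and HIF1A was no longer called (adjusted p = 0.0726), nor was it without knockdown replicate 2 (adjusted p = 0.0589). Granule genes that fell numbered 2 without knockdown replicate 1 and 3 without knockdown replicate 2, and 1 rose without control replicate 1. Hypoxia genes that fell numbered 2 without knockdown replicate 1 and 12 without control replicate 1.

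Of 37 ribosome biogenesis and MYC-related genes, 4 fell: NPM1 (−0.49), HSPD1 (−0.41), ODC1 (−0.56) and WDR12 (−0.49). The same number fell adjusted over the list alone (set adjusted p = 0.00245; adjusted p = 0.67 with an estimated correlation). None of the 4 was called without knockdown replicate 2, where the set was not lower either (adjusted p = 0.689). In that comparison the adjusted p was 0.0538 for NPM1, 0.248 for HSPD1, 0.0765 for ODC1 and 0.324 for WDR12. ODC1 and WDR12 were also not called without knockdown replicate 1 (adjusted p = 0.115 and 0.0609) or without control replicate 1 (adjusted p = 0.156 and 0.0577). Of 54 nuclear genes of oxidative phosphorylation, 3 fell, among them COX7C (−0.56) and ATP5F1A (−0.31), and 2 fell adjusted over the list alone. The set was lower, with a median of −0.12 (adjusted p = 0.00812; adjusted p = 0.664 with an estimated correlation). It was not lower without control replicate 1 (adjusted p = 0.0867) or knockdown replicate 2 (adjusted p = 0.563). The median was −0.24 without knockdown replicate 1, −0.03 without knockdown replicate 2 and −0.07 without control replicate 1. Genes of this list that fell numbered 5 without control replicate 2, and 1 without knockdown replicate 1 or 2. COX7C was not called without knockdown replicate 2 (adjusted p = 0.0858), nor ATP5F1A without knockdown replicate 1 or 2 (adjusted p = 0.149 and 0.346).

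Cell cycle genes did not move as sets. Of 43 genes of the G1/S transition and DNA replication, the thymidine kinase TK1 (0.48) and the cyclin CCNE2 (0.52) rose and MCM6 (−0.44) fell, with the same counts adjusted over the list alone. The median was −0.04 (−0.20 without knockdown replicate 1 and 0.11 without knockdown replicate 2), the direction of the set test up and its adjusted p 0.985. Leaving out any library made the G1/S set pass, with adjusted p from 0.0122 to 0.0439 and a direction that turned between libraries. Without control replicate 1, 8 of its genes rose, without knockdown replicate 2, 4 rose, and without control replicate 2, 4 fell. Of 42 mitotic genes, only the phosphatase CDC25B rose (0.67, adjusted p = 0.00304), and adjusted over the list alone 1 rose (set adjusted p = 0.483). In that list 2 genes rose and 2 fell without control replicate 1. TK1 and CCNE2 were not called without knockdown replicate 1 (adjusted p = 0.134 and 0.241), nor MCM6 without knockdown replicate 2 (adjusted p = 0.34).

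Markers of other cell types and control genes gave no set that passed. Of 6 measured T and NK cell markers, CD6 (1.61) and NKG7 (1.34) rose and CD4 (−0.37) and IL7R (−0.47) fell, with the same counts adjusted over the list alone (set adjusted p = 0.445). CD6, CD4 and IL7R were not called without knockdown replicate 2 (adjusted p = 0.0517, 0.126 and 0.392), and CD4 not without knockdown replicate 1 or control replicate 2 (adjusted p = 0.185 and 0.054). Of 7 dendritic cell markers, FSCN1 rose (0.47, adjusted p = 0.0102), though not without knockdown replicate 1 or 2 (adjusted p = 0.0571 and 0.0762). In all, 2 rose adjusted over the list alone, and the set did not pass (adjusted p = 0.0875), although it did without control replicate 2 (adjusted p = 0.0261) and with no filter on low counts (adjusted p = 0.03). Fewer than 5 members were measured of the B cell, erythroid and megakaryocyte, and epithelial and fibroblast lists, which were not tested as sets. Among these, the B cell scaffold BANK1 fell from 28.9 ± 1.6 to 15.2 ± 0.69 CPM (adjusted p = 0.000955), and PAX5, EPOR and KRT8 had log2 fold changes of 0.19, −0.02 and 0.04. Of 13 genes often used as controls, TFRC (0.91) and B2M (0.38) rose and RPLP0 (−0.43) fell, while GAPDH and ACTB had 0.04 and −0.17 (set adjusted p = 0.772; 2 rose and 1 fell adjusted over the list alone). B2M was not called without knockdown replicate 1 or control replicate 1 (adjusted p = 0.143 and 0.0527), nor RPLP0 without knockdown replicate 1 (adjusted p = 0.0547), and without control replicate 2, 2 of these control genes fell.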

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

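The GC correction and the newer quasi-likelihood setting were chosen after the results were seen, and the other alternatives before the data were examined. All 147 called genes named under the rule kept their direction under every alternative that gave a value. Against 1058 genes higher and 858 lower, no filter on low counts gave 381 and 204 over 32260 genes in place of 17032. DESeq2 gave 691 and 493, of which 688 and 493 were among the main calls. An adjusted p under 0.01 gave 501 and 344 and a fold above 1.5 by glmTreat 151 and 60, both stricter by construction. Leaving out a replicate gave 384 to 1186 genes higher and 190 to 1023 lower, both lowest without knockdown replicate 1. The replicate numbers are not stated to pair the samples, and the deviations of same-numbered libraries correlated only weakly, at 0.108. The second principal component split both groups by number. With 2 libraries a group, even a weak positive correlation can give that split, so it is no separate evidence of pairing. With the number as a block, 1710 were higher and 1550 lower, including all main calls. For the unfiltered, DESeq2, left-out and blocked values the cause was not tested. The GC correction gave 1320 and 1070, and the other settings stayed within 1.5 times.

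For gene lists, 20 were higher and 5 lower, against 0 and 0 with an estimated correlation (3 and 0 at an unadjusted p under 0.05) and 1 (p53 targets, adjusted p = 0.0288) and 0 with fry, which tests a list against no change and not against other genes. With 2 libraries a group, an estimated correlation also rests on 2 residual degrees per gene. The estimates ran from −0.0141 (metallothioneins) to 0.738 (ribosome biogenesis), with 0.517 for interferon-stimulated and 0.594 for ribosomal protein genes. The preset of 0.01 treats the genes of a list as nearly independent, so the smallest adjusted p-values by camera may be far too small. Leaving out a replicate gave 20 to 23 lists higher and 3 to 7 lower. Camera does not use the quasi-likelihood setting or the gene threshold, so no list values exist for those. The planned legacy setting is the installed default and moved nothing. The AMANZI region ranged from 0.65 to 1.41 and passed in 8 of 15 alternatives, with an adjusted p of 0.147 by DESeq2 and 0.138 without the filter. IL1B ranged from 1.85 to 1.91 and passed in all 16, TNF was lost only under glmTreat (adjusted p = 0.0749), and CXCL8, not called, passed in 6 of 16. Of the 147 named calls, 96 were lost under glmTreat, 47 without the filter, 43 without knockdown replicate 1, 31 at 0.01, 26 without knockdown replicate 2, 12 by DESeq2, 9 and 6 without control replicates 2 and 1, and 1 with the GC correction. Depth limits IL37, IL6, IL10, IFNB1 and IFNA1, which were below the filter.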

Other observations

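The noncoding comparison and the tests of the AMANZI region, of interferon beta, of library scaling and of the genes nearest AMANZI were chosen after the results were seen. The integrated stress response list, fixed beforehand, split in the libraries labelled AMANZI knockdown. Of 32 genes controlled by ATF4, 3 rose and 9 fell, and 4 rose and 10 fell adjusted over the list alone. ATF3 rose by 1.42 and SLC7A11 by 0.95, while PSAT1, a serine synthesis enzyme, fell from 314 ± 41 to 192 ± 3.2 CPM (log2 fold change −0.71, adjusted p = 0.000673) and DDIT4 by 0.66. The set did not pass (adjusted p = 0.0818). It passed without control replicate 2 (adjusted p = 6.37e-05), and also with no filter, DESeq2, limma-voom, the GC correction or the replicate block (adjusted p = 0.044, 0.0156, 0.0342, 0.0289 and 0.0356). Without knockdown replicate 1, 3 of these genes fell, and without control replicate 1, 6 rose. Of 20 genes of sterol efflux and lipid handling, 4 rose and 2 fell (6 and 3 adjusted over the list alone). The lipid droplet protein HILPDA fell from 62.6 ± 9.8 to 22 ± 0.18 CPM (log2 fold change −1.51, adjusted p = 2.31e-05) and the acyl-CoA synthetase ACSL1 rose by 1.03. That set did not pass (adjusted p = 0.135), except without control replicate 2 (adjusted p = 0.00701) or with no filter (adjusted p = 0.0321).

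Complement and coagulation genes went both ways: 4 of 21 rose, led by C3 (0.93, adjusted p = 6.79e-05) and THBD (0.70), and C3AR1 and F13A1 fell, with the same counts adjusted over the list alone. C3AR1 and F13A1 were not called without knockdown replicate 1 (adjusted p = 0.202 and 0.15) or 2 (adjusted p = 0.0785 and 0.159), nor F13A1 without control replicate 2 (adjusted p = 0.153). The median was −0.04, 0.08 without knockdown replicate 1 and 0.12 without control replicate 2, and the direction of the set test up (adjusted p = 0.25). Of 32 chromatin and looping genes, CREBBP rose and NIPBL and WDR5 fell, the same counts adjusted over the list alone (set adjusted p = 0.178). WDR5, a subunit of histone methyltransferase complexes, fell from 148 ± 8.3 to 101 ± 2.7 CPM (log2 fold change −0.55, adjusted p = 0.00252, or 0.0581 without knockdown replicate 1). CREBBP and NIPBL were not called without knockdown replicate 1 (adjusted p = 0.147 and 0.219), knockdown replicate 2 (adjusted p = 0.141 and 0.102) or control replicate 2 (adjusted p = 0.0816 and 0.0732). Of 16 prostaglandin and arachidonate genes, PLA2G4C rose and PLA2G4A and LTB4R fell (3 rose and 2 fell adjusted over the list alone, set adjusted p = 0.445). PLA2G4A and LTB4R were not called without knockdown replicate 1 (adjusted p = 0.239 and 0.226), PLA2G4A without control replicate 2 (adjusted p = 0.061) and LTB4R without control replicate 1 (adjusted p = 0.0764), and without control replicate 2, 5 genes of the list rose.

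Of 8 metallothionein and zinc genes, the exporter SLC30A1 rose (1.26, adjusted p = 0.000465), and 2 rose adjusted over the list alone. The set did not pass (adjusted p = 0.106), except without control replicate 2 or knockdown replicate 2 (adjusted p = 0.0441 and 0.0361) or with no filter (adjusted p = 0.03). Of 13 mitochondrially encoded genes, MT-ATP8 rose (0.64, adjusted p = 0.0021; 1 adjusted over the list alone, set adjusted p = 0.171). That set passed without control replicate 1 or knockdown replicate 2 (adjusted p = 0.0345 and 0.0139) and with no filter or the GC correction (adjusted p = 0.0444 and 0.0423), and without control replicate 1, 4 of its genes rose, while 1 fell without control replicate 2. Of 19 heat shock genes, HSPD1 fell (1 adjusted over the list alone, set adjusted p = 0.445), though not without knockdown replicate 2 (adjusted p = 0.248). Without control replicate 1, 1 heat shock gene rose and 2 fell, and without control replicate 2, 3 fell. Of 22 genes of RNase H and RNA decay, MTREX fell (0 adjusted over the list alone, set adjusted p = 0.336). It was not called without knockdown replicate 1, knockdown replicate 2 or control replicate 2 (adjusted p = 0.216, 0.28 and 0.112). Noncoding genes made up 147 of the noncoding and protein-coding genes that fell (18.3%) and 51 of those that rose (5.00%), against 16.5% of those tested (lower against higher, Fisher's exact p = 7.51e-20, genes not independent). The contrast lay mainly in their low share among genes that rose, with an odds ratio of 5.10 (95% interval 3.60 to 7.21) stratified by level. It was not stratified by GC content or transcript length. Over 12514 protein-coding genes the fold change rose with GC content (Spearman correlation 0.174), so a GC trend stays open as a source of the contrast. TIMP3, named after its values were seen, was among the most abundant transcripts and fell by 1.15 on the log2 scale (adjusted p = 9.82e-06).

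The region of AMANZI was higher in the libraries labelled AMANZI knockdown. Reads arising in proportion to IL1B transcripts would give it the same fold change, and it lay below that of IL1B by more than 2 standard errors (difference −0.897, SE 0.293). Without control replicate 1 it did not (difference −0.478, SE 0.378), so such reads cannot be told apart from other sources with so few counts. An exchange of the group labels cannot be told apart from a true rise, since all 4 libraries would be out of place and the region's log2 fold change of 0.974 fits both. The oligonucleotide's sequence and the strand of AMANZI were not used here.

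Interferon-stimulated genes rose together. A scaling factor moves every gene of a library alike. The median log2 fold change over all tested genes was −0.0113, but TMM scaling centres it by design, so it tests nothing by itself. No factor can change the gap between it and the 0.93 of this list. That gap argues against library scaling as its source, while a shift common to all genes cannot be seen after scaling. The list's median was 0.923 with no composition factor and 0.925 by median of ratios. With TMM factors of 0.990 to 1.01 these could differ little. Ribosomal protein genes had a median of −0.468 (SD over genes 0.134), but they were chosen after the results were seen and add no independent test. Innate sensing of the targeting LNA as foreign nucleic acid, whatever its target, cannot be told apart from an effect of AMANZI, because the labels name no second LNA for either group. IFNB1 counts were 7 against 2 (exact binomial p = 0.0977, two-sided, for counting error alone and not the spread between libraries), too few to decide. A biological link between AMANZI and interferon genes stays open.

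Ribosomal protein genes fell together. Genes outside the list matched on length, GC content and level had a median log2 fold change of 0.00653 over 1000 draws (−0.0786 to 0.0885), which argues against a trend with transcript length or GC content. The median over all tested genes, −0.0113, is centred by TMM scaling and tests nothing by itself. No factor can change the gap between it and the −0.468 of this list. That gap argues against library scaling as its source, while a shift common to all genes cannot be seen after scaling. The list's median was −0.467 with no composition factor and −0.466 by median of ratios. With TMM factors of 0.990 to 1.01 these could differ little. The cholesterol genes had a median of 0.534 (SD over genes 0.232), but they were chosen after the results were seen and add no independent test. Reads shared with pseudogenes and a biological effect of the LNA stay open, and a lower abundance of ribosomal protein messenger RNA remains a hypothesis.

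An effect on the genes nearest AMANZI was also tried as a hypothesis. Genes were taken by rank of distance with no limit on it, so an effect confined to the closest was not tested separately. Of the 20 nearest tested protein-coding genes 4 were called (BCL2L11, IL1B, IL1RN and MERTK), or 20%, against 1621 of 12494 others (Fisher's exact p = 0.318, two-sided). With 20 genes, a concentration of changes around the locus cannot be told apart from none.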
